A study of Mus musculus with 8 samples.

How the data were processed

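Total RNA from mouse embryonic fibroblasts (MEFs) was hybridised to single-colour Illumina bead arrays, 8 arrays in 4 groups of 2. MEFs are connective tissue cells grown out of mouse embryos. The groups are wild-type and Ticam1 knockout cells, each transfected with c-di-GMP or given DMSO. Ticam1 encodes TRIF, the adaptor protein of Toll-like receptors 3 and 4. c-di-GMP is a bacterial second messenger that mammalian cells sense through the adaptor protein STING. Per the labels' protocols, c-di-GMP was delivered at 8 µg/ml with a lipofection reagent for 30 min, control cells had the same amount of DMSO, RNA was taken 4 h after transfection, and the medium held 10% serum. Group and replicate number come from the sample titles, where the knockout is written TICAM. Nothing in the labels says that replicates were separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical.

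The authors deposited a table of non-normalized probe intensity, with 1 signal per probe and array, exported from GenomeStudio 2010.2 per the submitters' processing notes. Beside each signal stands a detection p-value, per the file headers. It was taken to compare the probe with negative controls, which the headers do not state. Background handling before export is not given in the sources used here. The authors also deposited a table of normalized intensity on a linear scale, in which the quartiles of the 8 arrays are nearly equal, so it was taken as quantile normalized. Its method is not given in the sources used here. The value table of the series holds the same normalized values, with 0 cells that differ. The p-values of both deposited tables differ in 12 cells.

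The tables hold 25697 probes and 18138 gene names. Names were updated through the mouse gene table of the GRCm38.p6 assembly to 17891 current symbols: 20733 probes matched exactly, 122 by gene number and 3872 by a synonym, and 939 kept the name of the file. A further 31 probes carry a date that a spreadsheet put in place of a name. They were left unnamed. No chromosome coordinates are printed, since the files name no genome build.

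Non-normalized signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp background correction through the detection p-values, offset 16, quantile normalization, log2). A probe was kept with a detection p under 0.05 on at least 2 of the 8 arrays, which left 13026 probes. Each gene was represented by the probe with the highest mean over all arrays, which gave 9554 genes, of which 2461 had more than 1 detected probe. The limma model had 1 mean per group and no other term, with all 8 arrays sharing 1 estimate of the spread (4 residual degrees of freedom, 2.77 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over the 9554 genes of each comparison and a threshold of 0.05. The comparisons are c-di-GMP against DMSO in wild-type cells, the same in knockout cells, the difference between these responses (knockout minus wild type), and knockout against wild type under DMSO. Unless stated otherwise, an error after a log2 difference is the model's standard error (SE), and n = 2 arrays per group.

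A gene with a detection p of 0.05 or more on every array of a group has only a bound there. The ratio is then written as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the gene's own signal, on normalized log2 values. The number of arrays limits the precision. Simulated data for the 9554 genes were made from these arrays, with known changes planted in some of the genes. In the wild-type comparison the model recovered 34.3% of 67 genes with a log2 change of 2 and 77.3% of 66 genes with a change of 3. For the knockout comparison these shares were 35.8% and 68.2%, for the difference of responses 4.48% and 48.5%, and for the genotypes under DMSO 53.7% and 77.3%. At a log2 change of 1 the share was 1.49% for the genotypes under DMSO and 0% for the other comparisons. No unchanged gene was called in these runs. Before the planted changes, each simulated gene had the same mean in every group, and no floor at background was set. The shares therefore need not hold for genes that read at background in a group. A list raised by 1 in the simulated wild-type response was called at a limma camera adjusted p = 2.81e-96, with 0 of the 23 other lists called. The simulated genes varied independently of each other, so this run cannot show how often lists of correlated genes are called falsely.

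The second knockout DMSO array carried little signal, as given with the results. Every comparison was therefore also fitted without it, which leaves that group with 1 array that is assumed to vary like the other groups. Without it the simulated shares for a log2 change of 2 were 100% in the wild-type and knockout comparisons and 97% for the difference of responses, with 5, 7 and 8 unchanged genes called.

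Before the data were examined, 26 gene lists with 720 genes were fixed, of which 662 are on the array. They cover interferon ligands, interferon-stimulated genes, interferon-inducible GTPases, antigen presentation, cytokines and chemokines, NF-kB targets and feedback, the STING and Toll-like receptor pathways, immediate early genes, the unfolded protein response, heat and oxidative stress, cell death, p53 targets, proliferation, sterol synthesis, glycolysis and hypoxia, fibroblast matrix, smooth muscle contractile genes, developmental and positional genes and imprinted genes. Markers of other cell types that such a culture could hold make up the rest: leukocytes, endothelium, epithelium, neural cells, skeletal and cardiac muscle, cartilage, fat and bone, and erythroid cells. Lists with at least 5 tested genes were tested with camera of limma (preset correlation 0.01, Benjamini-Hochberg over the 24 lists tested), with camera with an estimated correlation and with fry beside it. The epithelial list had 2 tested genes and the erythroid list 0, so neither was tested.

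The genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls past the threshold whose arrays do not overlap between groups. Where fewer than 5 genes pass, it takes the 10 smallest p-values. It adds Ticam1, Ifnb1, Cxcl10, Ccl5, Ifit1, Isg15, Irf7, Il6, Tnf and Sting1 whatever their values, and up to 4 genes per list with the smallest p. The Ifit1 probe was not detected on enough arrays to be tested, and no probe of the tables is named Sting1 or by its older symbol. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here.

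Alternatives fixed before the data were examined were no background correction, median scaling between arrays, the authors' normalized values, no filter on detection, a detection p under 0.01, every probe, the replicate number as a block, only the arrays of the comparison, a variance trend with robust fitting, array weights, a minimum log2 difference of 1, and each array left out. A slide block was not run, because the files give no slide. The authors' values without the second knockout DMSO array were added after the data were seen.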

Results

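The series profiled 8 arrays of MEFs to ask which transcripts change after transfection of c-di-GMP and whether Ticam1 matters for that change. Wild-type and knockout cells under c-di-GMP or DMSO had 2 arrays each. The mean signal was 252.6 to 648.9 on 7 arrays and 225.9 on the second knockout DMSO array. On the 7 arrays between 11254 and 11657 of the 25697 probes were detected, and the signal at the 99th percentile was 38.3 to 83 times that at the 5th. On the second knockout DMSO array 6468 probes were detected, this ratio was 7.55, and the lowest detected log2 signal was 7.53, against 5.36 to 5.45 on the others. Its correlation with the first knockout DMSO array was 0.815 across probes, while the arrays of the other groups correlated at 0.978 to 0.991. No arrays of a group held the same values. Quantile normalization left the median log2 difference over all genes at -0.06 in the wild-type response, 0.10 in the knockout response, 0.16 in the difference of responses and -0.11 between genotypes under DMSO. With median scaling these medians were -0.24, 0.93, 1.17 and -0.62. The direction of a gene list is therefore given relative to all genes, as the camera test does.

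**Figure D1:**
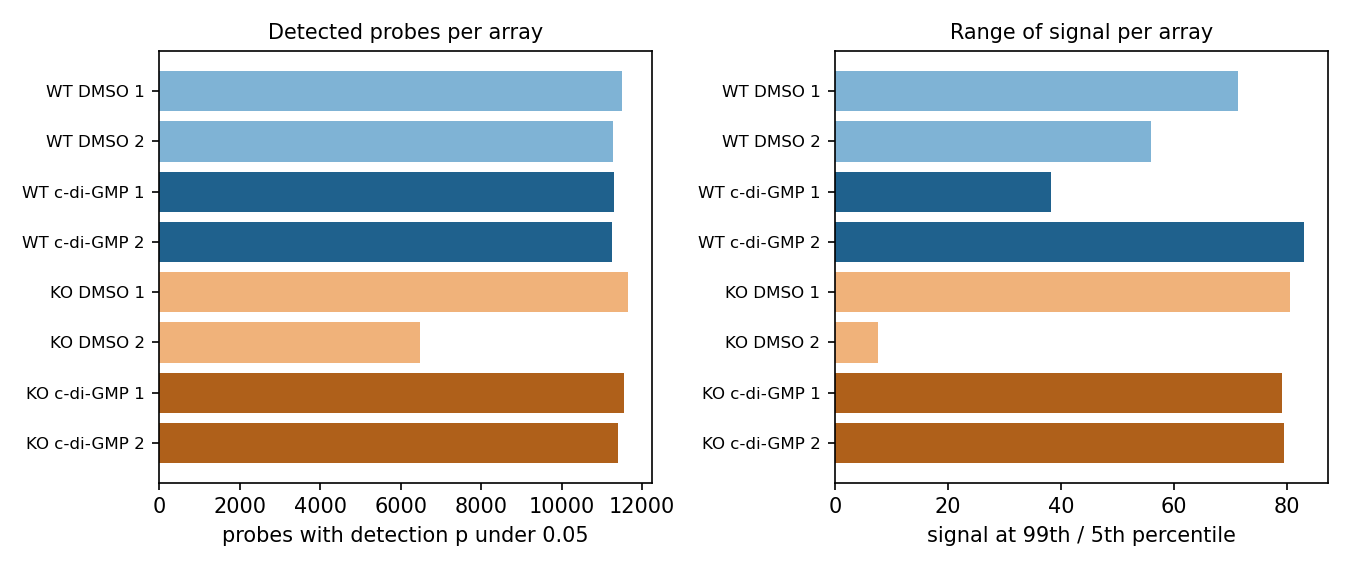
Probes with a detection p under 0.05 (left) and the signal at the 99th over the 5th percentile (right), 1 bar per array. The second knockout (KO) DMSO array stands at 6468 probes and a ratio of 7.55, below the 7 others.

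Ticam1, the targeted gene, read near background in every sample. The signals of its tested probe were 90.7 and 157.2 in wild-type cells with c-di-GMP, 156.1 and 109.3 with DMSO, 124.6 and 157.5 in knockout cells with c-di-GMP and 164.5 and 167.9 with DMSO. It passed the detection threshold on 3 of these 8 arrays, and the other probe, at 85.3 to 147.5, on 0. Knockout and wild-type cells under DMSO differed by 0.14 ± 0.32 (log2, adjusted p = 0.783). Where the probes lie relative to the deleted part is not known, so Ticam1 checks no label here.

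In wild-type cells, c-di-GMP raised interferon beta, chemokines and interferon-stimulated genes. Ifnb1, which encodes interferon beta, rose from 4.90 ± 0.21 to 9.73 ± 0.19 (mean log2 intensity ± SD, n = 2). As it was not detected on either DMSO array, the rise was at least 19.8-fold (adjusted p = 0.00412). Cxcl10 rose from 11.12 ± 0.38 to 14.39 ± 0.13 and Ccl5 from 10.02 ± 0.01 to 13.39 ± 0.02, differences of 3.27 ± 0.30 and 3.37 ± 0.33 (adjusted p = 0.0124 and 0.017). Both encode chemokines that attract T cells. Calhm6, an interferon-induced membrane protein gene, rose by at least 23.9-fold (adjusted p = 0.00196). Oasl1, a regulator of Irf7 translation, rose from 6.92 ± 0.29 to 11.12 ± 0.18, and Cd274, which encodes the inhibitory ligand PD-L1, by 3.85 ± 0.30. Has2, a hyaluronan synthase gene, rose by 3.64 ± 0.52, Cxcl9 by 3.58 ± 0.28, Ccrl2 by 3.56 ± 0.35, Gbp5 by 3.50 ± 0.40, Cd40 by 3.24 ± 0.26 and the antiviral gene Rsad2 by 3.17 ± 0.27. Adjusted p for these 8 genes lay between 0.00444 and 0.044.

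Altogether 56 genes rose and 1 fell of the 9554 tested in limma. The fall was in Ppp1r3c, a subunit gene of the phosphatase that activates glycogen synthesis, which was lower by at least 5.8-fold (adjusted p = 0.0214). For every gene named as changed, both c-di-GMP arrays lay on the same side of both DMSO arrays, which the naming rule requires of the largest changes. Of the genes fixed in advance, Il6 differed by 1.71 ± 0.28 (adjusted p = 0.0726), Tnf by 1.80 ± 0.41 (0.201), Irf7 by 2.07 ± 0.59 (0.362) and Isg15 by 0.65 ± 0.23 (0.576), and these did not pass. The count changed whichever array was left out. It was higher without either knockout DMSO array and lower without any other array, knockout or wild-type. Leaving out a knockout array changed only the spread and not the wild-type differences. The median SE was 0.376 with all arrays and 0.198 without the second knockout DMSO array. Each of these fits leaves 1 array in a group, so their counts cannot show whether the wild-type response depends on a single array. With the second knockout DMSO array left out, all 57 calls were kept, and Il6, Tnf and Irf7 passed (adjusted p = 0.00609, 0.0244 and 0.00489), while Isg15 did not (0.0574). Median scaling gave 0 calls in limma, with 110 genes at an unadjusted p under 0.05, against 640 with quantile normalization. Knockout arrays enter this comparison only through the shared estimate of the spread.

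**Figure D2:**
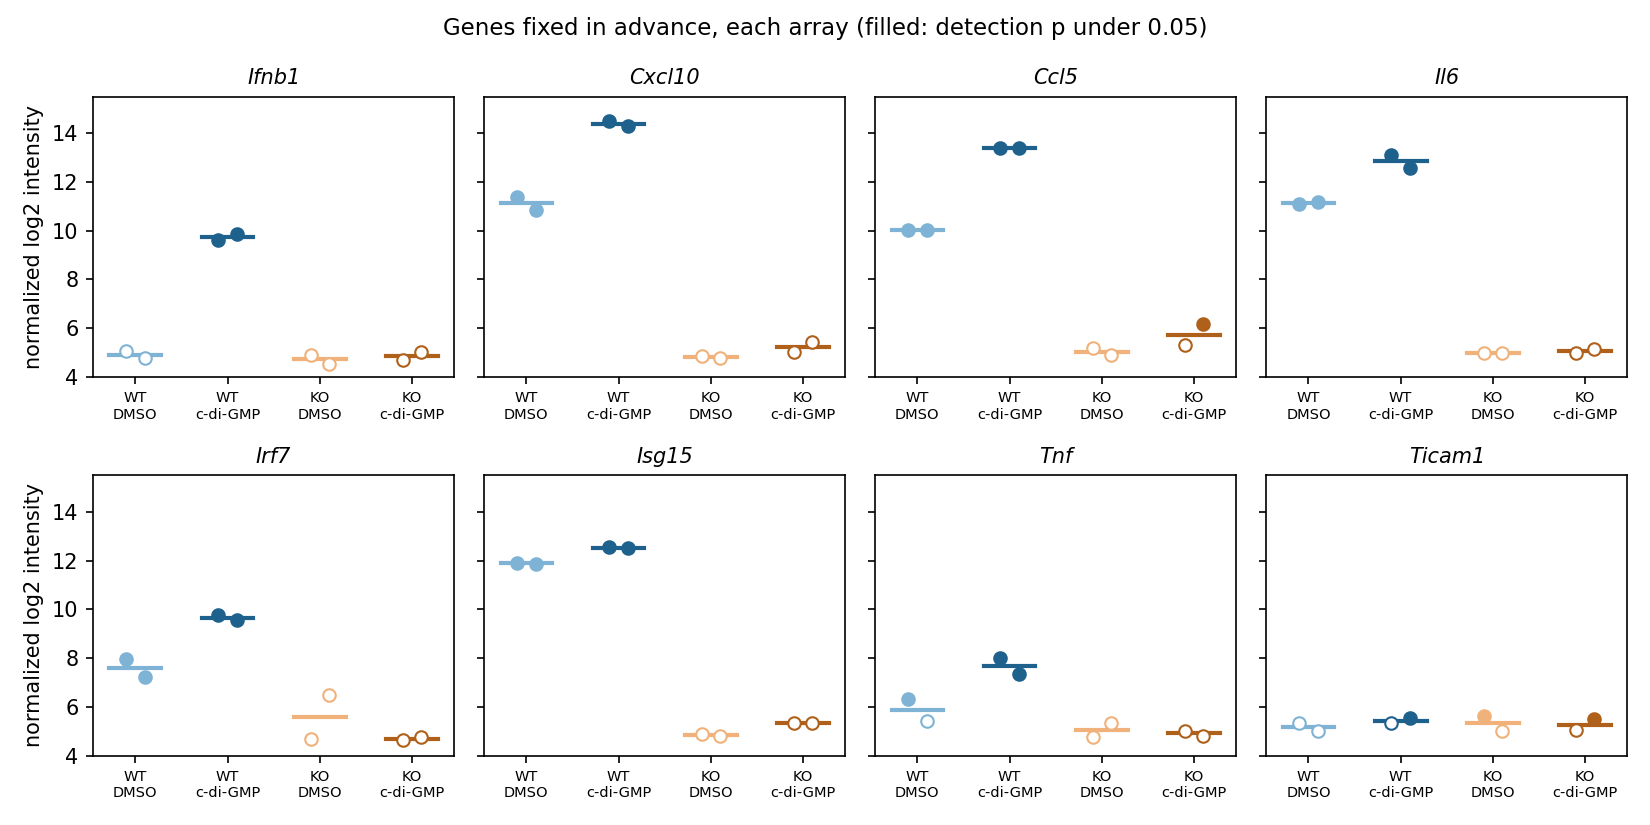
Normalized log2 intensity of 8 genes fixed in advance, 1 point per array and a line at each group mean of 2 arrays, filled where the detection p was under 0.05. Ifnb1 reaches 9.73 in wild-type (WT) cells with c-di-GMP, while Ifnb1, Cxcl10, Il6 and Isg15 are not detected on any knockout (KO) array.

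Interferon-stimulated genes rose as a group in wild-type cells, with a median log2 difference of 1.37 over 50 genes, or 1.32 with undetected genes at their bounds (camera adjusted p = 5.93e-53, and adjusted p = 0.00484 with an estimated correlation). Of these 11 rose over all genes and 36 adjusted over the list alone, and 49 of the 50 differences were positive. Besides Oasl1 and Rsad2 they included Mx1 (3.02 ± 0.25) and Cmpk2 (2.93 ± 0.25), both with adjusted p = 0.0105. Interferon-inducible GTPases, which act against intracellular pathogens, had a median of 1.92, with 4 of 11 rising and 9 adjusted over the list alone. The 4 were Gbp5, Tgtp1 (2.97 ± 0.32), Igtp (2.22 ± 0.25) and Irgm2 (1.92 ± 0.26), and the list passed at adjusted p = 1.23e-19 and, with an estimated correlation, adjusted p = 0.00484. Antigen presentation genes had a median of 1.06, or 1.01 at bounds (adjusted p = 5.92e-19, and adjusted p = 0.00859 with an estimated correlation, but adjusted p = 0.0817 with an estimated correlation without the second knockout DMSO array). Among its 19 genes 2 rose, 13 adjusted over the list alone: Nlrc5, the transactivator of MHC class I genes, by 3.08 ± 0.27 and the immunoproteasome gene Psmb9 by 2.45 ± 0.33. Cytokines and chemokines had a median of 0.83, or 0.75 at bounds, with 4 of 27 rising and 9 adjusted over the list alone, including Il15 at 2.80 ± 0.30 (list adjusted p = 5.68e-18, and adjusted p = 0.00484 with an estimated correlation).

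NF-kB targets and feedback genes had a median of 0.49, with 3 of 30 rising and 7 adjusted over the list alone. These were Cd40, Tnfaip3, which encodes the inhibitor A20, by 2.12 ± 0.28, and Ripk2 by 2.08 ± 0.29 (list adjusted p = 1.61e-11, and adjusted p = 0.0465 with an estimated correlation). Of 21 cell death genes 1 rose, Casp4 by 2.40 ± 0.34, and 5 adjusted over the list alone, at a median of 0.46 (adjusted p = 0.00023, and adjusted p = 0.0465 with an estimated correlation, but adjusted p = 0.102 with an estimated correlation without the second knockout DMSO array). Among 5 interferon ligand genes Ifnb1 rose, and 2 passed adjusted over the list alone, the other being Ifna4, at least 1.49-fold higher and not detected on either DMSO array. The ligand list had a median of 0.36, or 0.32 at bounds, with adjusted p = 0.00041, and adjusted p = 0.0589 with an estimated correlation. Of 16 ligand genes on the array only these 5 passed the detection filter, Ifnb1 solely through the 2 wild-type c-di-GMP arrays. The ligand list was thus partly picked by the group in which it was higher. Immediate early genes had a median of 0.35, or 0.21 at bounds, with 0 of 26 passing over all genes in limma, 8 at an unadjusted p under 0.05 and 1 adjusted over the list alone, Atf3, at least 4.13-fold higher and not detected on either DMSO array. That list passed at adjusted p = 0.00704, but had adjusted p = 0.426 with an estimated correlation. Sterol synthesis genes had a median of -0.41 (adjusted p = 0.0048, and adjusted p = 0.0737 with an estimated correlation), with 0 of 25 passing over all genes in limma, 4 at an unadjusted p under 0.05 and 1 adjusted over the list alone. That gene was Ch25h at 1.44 ± 0.25, an interferon-induced enzyme that makes an oxysterol, while Stard4 stood at -1.37 ± 0.41 and Mvd at -1.12 ± 0.41. Without the second wild-type c-di-GMP array the sterol list had adjusted p = 0.0613. The ligand median was 0.78 without the first and 0.54 without the second wild-type c-di-GMP array, and the immediate early median 0.23 without the first wild-type c-di-GMP and 0.21 without the second wild-type DMSO array. Of the 9 lists passing in camera, fry, which asks whether a list moves without comparing it with other genes, passed all but immediate early genes (adjusted p = 0.266).

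The other 15 lists did not pass in wild-type cells. Among them, the STING and Toll-like receptor list held 1 riser, Tlr3, a receptor for double-stranded RNA, by 2.62 ± 0.30, with a list adjusted p of 0.409. Smallest among the 15 was the unfolded protein response at adjusted p = 0.169. Lists at 0.798 included imprinted genes and the markers of neural, muscle, and cartilage, fat and bone cells. Leukocyte markers had a median of -0.13 (adjusted p = 0.409, but 0.0228 without the first wild-type c-di-GMP array). Proliferation genes stood at -0.10 (0.397), fibroblast matrix at 0.04 (0.318), heat and oxidative stress at 0.18 (0.23), p53 targets at -0.08 (0.636), glycolysis and hypoxia at 0.03 (mean -0.07, 0.789), smooth muscle genes at -0.18 (0.36, but 0.0261 by fry), positional genes at -0.11 (0.409) and endothelial markers at -0.13 (0.636).

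In knockout cells no such response was detected. Ifnb1 differed by 0.13 ± 0.29 between c-di-GMP and DMSO, Cxcl10 by 0.38 ± 0.30, Il6 by 0.08 ± 0.28 and Isg15 by 0.49 ± 0.23, and none of these was detected on any of the 4 knockout arrays. With c-di-GMP, some readings lay just over the detection threshold. The detection p was 0.18 and 0.0501 for Cxcl10 and 0.0551 and 0.0677 for Isg15, against 0.269 to 0.530 under DMSO. For Ifnb1 and Il6 with c-di-GMP it was 0.114 to 0.645. Ccl5, detected on 1 knockout array, differed by 0.71 ± 0.33 (adjusted p = 0.529). Irf7 and Tnf, also undetected, read -0.88 ± 0.59 and -0.15 ± 0.41, and both negative values come from the second knockout DMSO array. Irf7 read 6.50 there and 4.66 on the first, against 4.64 and 4.75 with c-di-GMP. Tnf read 5.32 and 4.78, against 5.01 and 4.80. Interferon-stimulated genes had a median of 0.02, -0.08 relative to all genes, with 26 of 50 positive (camera adjusted p = 0.871). At the bounds set by detection, which leave 29 of the 50 undetected in at least 1 of the groups, their median was 0. Of the 56 genes that rose in wild-type cells, 37 were not detected on any knockout array. The smallest p-values, none of which passed (adjusted p = 0.529), belonged to 10 genes, each undetected on at least 1 of the 4 knockout arrays. The matrix gene Thbs1 (1.71 ± 0.44), Shmt1 (1.42 ± 0.38), Ado (1.13 ± 0.31) and Ppp1cc (1.28 ± 0.37) were detected on 1 of the 2 DMSO arrays. Sebox, Rnft1, Fcer1a and Serpina3n were not detected on either DMSO array, with c-di-GMP readings at least 1.13-fold higher for Sebox, at least 1.19-fold for Rnft1 and no bound above 1 for the other two. Myo7b and Col9a1 were not detected on either c-di-GMP array, with readings at least 1.47-fold and at least 1.78-fold lower.

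Limma called 0 of 9554 genes in knockout cells, with 254 at an unadjusted p under 0.05. Without the second knockout DMSO array it also called 0, with 221 at an unadjusted p under 0.05, and the 56 wild-type risers then had a median knockout change of 0.01 (quartiles -0.07 and 0.16), against 2.54 in wild-type cells. Without the first knockout DMSO array, which leaves the array of weak signal as the only control, it called 5487 genes. The wild-type median of 2.54 is high by selection, since the risers were picked for their wild-type change. No list passed in knockout cells with all 8 arrays (adjusted p from 0.29 to 0.957), the lowest being NF-kB targets and immediate early genes. Under median scaling, where the median of all genes was 0.93, the interferon-stimulated list lay 0.81 below it (-0.81, adjusted p = 2.68e-06). Without the second knockout DMSO array that scaling put the list 0.08 above all genes.

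**Figure D3:**
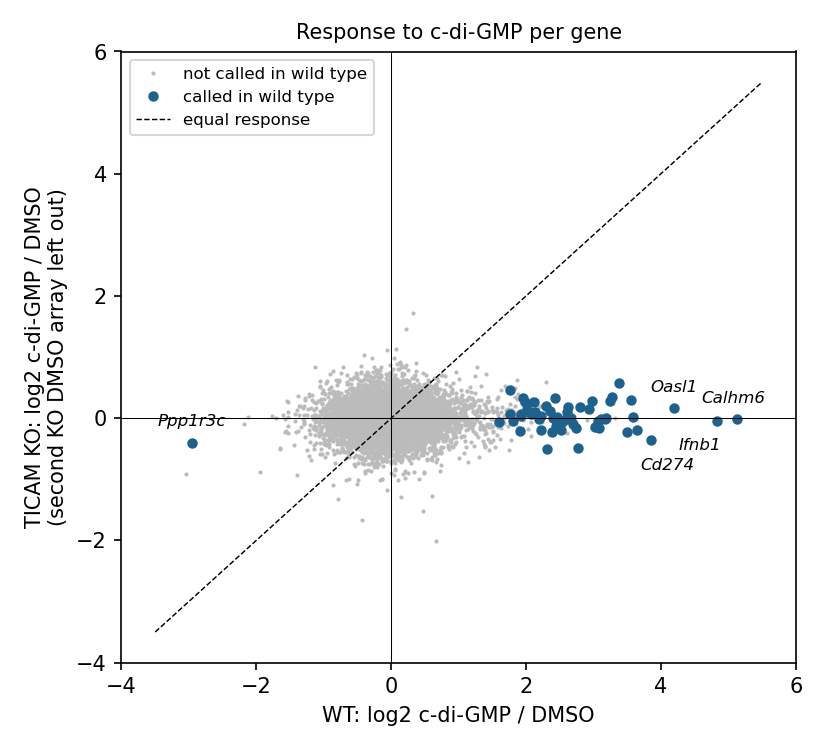
Log2 difference of c-di-GMP against DMSO per gene in wild-type cells (x axis) and in TICAM knockout (KO) cells without the second knockout DMSO array (y axis). Blue points are the 57 genes called in wild-type cells with all 8 arrays. They spread along the x axis, with a median knockout change of 0.01 for the 56 that rose. These were picked for their wild-type change, so lying below the dashed line of equal response was largely set in advance. Of the 56, 37 were detected on no knockout array.

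The difference between the responses was tested itself. It was negative, meaning a smaller response in knockout cells, for Calhm6 (-5.23 ± 0.35, adjusted p = 0.0173), Ifnb1 (-4.70 ± 0.40, adjusted p = 0.0419), Oasl1 (-4.12 ± 0.38, adjusted p = 0.0419) and Cd274 (-4.47 ± 0.42, adjusted p = 0.0419). Calhm6, Ifnb1 and Oasl1 were detected on 0 of the 4 knockout arrays and Cd274 on 1, so the knockout part of each difference rests on readings at background. Calhm6 and Ifnb1 were also undetected on both wild-type DMSO arrays, and their differences are fitted values, not measured sizes. Next by p, without passing, came Nlrc5 (-3.48 ± 0.38), Cxcl9 (-3.59 ± 0.40) and Mx1 (-3.11 ± 0.35), each with adjusted p = 0.0801, Rsad2 (-3.24 ± 0.38, 0.0922), and Cd40 (-2.96 ± 0.37) and Cmpk2 (-2.84 ± 0.36), both at 0.112. Cxcl10 stood at -2.89 ± 0.42 (0.162), Ccl5 at -2.67 ± 0.47 (0.225), Irf7 at -2.95 ± 0.83 (0.679), Il6 at -1.63 ± 0.40 (0.492), Tnf at -1.94 ± 0.57 (0.711) and Isg15 at -0.16 ± 0.32 (0.846). Of these further genes Ccl5 was detected on 1 knockout array and the others on 0.

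Limma called 4 genes for this difference, all lower, and 83 (79 lower, 4 higher) without the second knockout DMSO array, where Cxcl10 and Ccl5 passed (adjusted p = 0.0269 and 0.0418). The 4 higher, named after their values were seen, were Ppp1r3c (2.56 ± 0.32), Ddit4 (2.09 ± 0.27), Klhl21 (1.65 ± 0.26) and Rasl11a (2.13 ± 0.35), which had differences of -2.96, -2.18, -1.60 and -3.05 in wild-type cells. Ppp1r3c and Rasl11a were not detected on either wild-type c-di-GMP array, and Ppp1r3c on 0 of the 4 knockout arrays, so their values rest on readings at background. The count was 4636 without the first knockout DMSO array, and, in limma, 0 without any one of the other 6 arrays (218 to 469 genes at an unadjusted p under 0.05) and 0 under median scaling (72), against 506 with all 8 arrays and quantile normalization.

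By list, interferon-stimulated genes responded less in knockout cells by a median of -1.36 over 50 genes, -1.52 relative to all genes (camera adjusted p = 1.03e-30, and adjusted p = 0.0122 with an estimated correlation). There 1 gene was lower over all genes and 27 adjusted over the list alone. The GTPase list had a median of -1.75 (adjusted p = 1.77e-12, and adjusted p = 0.0122 with an estimated correlation), with 8 of 11 lower adjusted over the list alone, among them Gbp5 at -4.33 ± 0.57. Antigen presentation had a median of -1.05 (adjusted p = 5.86e-12, and adjusted p = 0.0212 with an estimated correlation), with 6 of 19 lower adjusted over the list alone, and cytokines and chemokines -0.80 (adjusted p = 4.28e-11, and adjusted p = 0.0122 with an estimated correlation), with 7 of 27. Over all genes tested, limma called 0 genes of these last 3 lists, with 9, 9 and 10 at an unadjusted p under 0.05. Without the second knockout DMSO array antigen presentation had adjusted p = 0.107 with an estimated correlation, and the other 3 lists 0.0487. By fry these 4 lists passed too (adjusted p from 0.00147 to 0.00258). In knockout cells 29 of the 50 interferon-stimulated genes and 8 of the 11 GTPase genes were undetected in at least 1 of the groups. So were 8 of 19 antigen presentation and 12 of 27 cytokine genes. The knockout part of their differences rests on readings at background, and single sizes such as that of Gbp5 may do so too.

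A further 4 lists passed in camera with the preset correlation but, with all 8 arrays, not with an estimated one. NF-kB genes had a median of -0.41 (adjusted p = 0.0012, and adjusted p = 0.207 with an estimated correlation), interferon ligands -0.37 (adjusted p = 0.00574, and adjusted p = 0.15 with an estimated correlation) and cell death genes -0.11 (adjusted p = 0.0418, and adjusted p = 0.206 with an estimated correlation). The ligand list holds Ifnb1, which passed the detection filter only through the 2 wild-type c-di-GMP arrays. NF-kB and cell death genes had medians of 0.48 and 0.70 under median scaling, below the 1.17 of all genes. The unfolded protein response list had a median of 0.49 (adjusted p = 0.046, and adjusted p = 0.207 with an estimated correlation), 0.34 above all genes. By fry, interferon ligands and cell death genes passed (adjusted p = 0.00355 and 0.00765), while NF-kB genes (0.172) and the unfolded protein response (0.105) did not. Without the second knockout DMSO array the medians of ligands, cell death genes and the unfolded protein response were -0.80, -0.48 and 0.25, and NF-kB genes, at -0.42, had adjusted p = 0.0487 with an estimated correlation. Without the first knockout DMSO array NF-kB genes, ligands, cell death genes and the unfolded protein response had medians of -0.14, -0.05, -0.04 and 0.72, with adjusted p = 0.451, 0.317, 0.4 and 0.254. Cell death genes also missed the threshold without the second wild-type c-di-GMP array (0.0615, median 0.03) or the first wild-type DMSO array (0.0639, median -0.07), and the unfolded protein response without those arrays (0.154 and 0.0639), the second wild-type DMSO array (0.0583) or the first knockout c-di-GMP array (0.0856). The cell death median was -0.17 without the first wild-type c-di-GMP array and -0.02 without the first knockout c-di-GMP array. Sterol synthesis genes, at a median of 0.58 (adjusted p = 0.0636), passed without the first wild-type c-di-GMP array (0.0444), the second knockout c-di-GMP array (0.0391) or the second knockout DMSO array (0.00105). The remaining 15 lists had adjusted p of 0.294 or more. By fry, sterol synthesis and smooth muscle genes passed as well (adjusted p = 0.00765 and 0.00394).

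Under DMSO, knockout and wild-type cells differed widely, and interferon-stimulated genes were lower in knockout cells before any c-di-GMP. Isg15, an ubiquitin-like antiviral protein gene, read 11.88 in wild-type cells and was not detected on either knockout DMSO array, at least 43.3-fold lower (adjusted p = 4.53e-05). Usp18 was at least 48.2-fold lower, Ifit3b at least 65.4-fold, Oasl2 at least 40.5-fold, Rsad2 at least 28.6-fold, Cxcl10 at least 25.6-fold, Il6 at least 25.8-fold and Ccl5 at least 11.9-fold (adjusted p from 4.53e-05 to 0.000348). Ifit3 (-7.32 ± 0.28) and Gbp2 (-6.57 ± 0.40) were detected on 1 of the 2 knockout DMSO arrays. Ifnb1 was not detected in either genotype under DMSO. Irf7 and Tnf, also undetected on both knockout DMSO arrays, did not pass (adjusted p = 0.0718 and 0.222), Irf7 reading at least 2.23-fold lower. The interferon-stimulated list had 35 of 50 genes lower over all genes and 42 adjusted over the list alone. Its median was -2.80, which is -2.69 relative to all genes and -1.81 with undetected genes at their bounds (adjusted p = 1.36e-23, and adjusted p = 0.0382 with an estimated correlation). By array, 48 to 50 of the 50 were detected in wild-type cells, 22 to 24 on 3 knockout arrays and 7 on the second knockout DMSO array. The GTPase list had 7 of 11 lower, 8 adjusted over the list alone, at a median of -4.54, or -3.70 at bounds (adjusted p = 5.16e-07, and adjusted p = 0.0382 with an estimated correlation). Both lists had adjusted p = 0.0987 with an estimated correlation, at medians of -2.59 and -3.96, without the second knockout DMSO array.

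Leukocyte markers moved with these genes. Lyz1, a lysozyme gene of myeloid cells, was at least 86.4-fold lower in knockout cells, Lyz2 at least 26.1-fold, the macrophage marker Adgre1 at least 8.97-fold and Laptm5 at least 8.15-fold (adjusted p from 4.53e-05 to 0.000123). Of 17 tested markers 7 were lower, also 7 adjusted over the list alone, at a median of -1.22, or -1.03 at bounds (adjusted p = 5.16e-07, and adjusted p = 0.0416 with an estimated correlation). Cytokines and chemokines had 13 lower and 2 higher of 27, and 14 and 3 adjusted over the list alone, with Ccl4 at least 14.7-fold and Ccl3 at least 5.93-fold lower. The median was -0.82, or -0.68 at bounds (adjusted p = 9.3e-05, and adjusted p = 0.0416 with an estimated correlation). Without the first knockout DMSO array, which leaves the weak array as the only knockout array under DMSO, cytokines had adjusted p = 0.0596 and leukocyte markers 0.0585. With the second one left out instead, both lists had adjusted p = 0.0987 with an estimated correlation, at medians of -1.13 for cytokines and -1.88 for leukocyte markers.

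Proliferation genes were higher in knockout cells, 20 of 35 over all genes and 22 adjusted over the list alone, with all 35 differences positive. Mcm2 and Mcm5, which encode parts of the replicative helicase, were higher by 2.62 ± 0.30 and 2.55 ± 0.27, and Birc5 by 3.02 ± 0.36, and Ccna2, the cyclin A gene of S phase, by at least 9.04-fold. The median was 1.47, which is 1.58 relative to all genes (adjusted p = 1.33e-12, and adjusted p = 0.0382 with an estimated correlation). It was 1.90 without the second knockout DMSO array (adjusted p = 0.131 with an estimated correlation).

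Among single genes, the glutamate transporter gene Slc1a3 was at least 79.1-fold higher in knockout cells (adjusted p = 4.53e-05), Hoxd8 at least 32.9-fold, the progenitor surface marker Cd34 at least 27.9-fold, Slc38a4 at least 15.9-fold and Slc6a15 at least 10.9-fold. Il1rl1, a receptor gene for interleukin 33, was higher by 5.60 ± 0.34, Dlk1 by 4.92 ± 0.38, Cck by 4.84 ± 0.39, the growth factor gene Igf2 by 4.74 ± 0.32, Kcnab1 by 4.71 ± 0.47 and Crabp1 by 4.67 ± 0.70. Besides the interferon and myeloid genes, genes lower in knockout cells included the cell cycle inhibitor gene Cdkn2b, at least 37.4-fold, the NADPH oxidase subunit gene Cyba, at least 39.2-fold, and the small heat shock protein gene Hspb1, at least 33.7-fold. Limma called 1213 genes between genotypes, 499 higher and 714 lower in knockout cells. The count was 95 (3 higher, 92 lower) under median scaling, where 21 of the 1213 genes changed sign. It was 2683 without the second and 6129 without the first knockout DMSO array, 272 and 270 without the first and second wild-type DMSO array, 742 without either wild-type c-di-GMP array and 553 without either knockout c-di-GMP array. All 1213 kept their call and direction without the second knockout DMSO array.

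A further 7 lists were lower in knockout cells in camera with the preset correlation but not with an estimated one, and also by fry (adjusted p from 3.81e-05 to 0.00994). Fibroblast matrix genes had 16 lower and 6 higher of 38, and 18 and 6 adjusted over the list alone, at a median of -1.26, or -1.13 at bounds (adjusted p = 0.00261, and adjusted p = 0.0852 with an estimated correlation). They included Thbs1 (-5.34 ± 0.44) and Mfap5 (-5.99 ± 0.54). NF-kB genes had 12 lower and 1 higher of 30, and 14 and 1 adjusted over the list alone, led by Lcn2 (-4.88 ± 0.34), at a median of -1.29, or -1.27 at bounds (adjusted p = 0.000234, and adjusted p = 0.117 with an estimated correlation). Antigen presentation had 8 of 19 lower, also 8 adjusted over the list alone, with H2-T23 at -2.18 ± 0.27 (median -0.61, -0.52 at bounds, adjusted p = 0.000462, and adjusted p = 0.0986 with an estimated correlation). Of 21 cell death genes 3 were lower, 8 adjusted over the list alone, among them Mlkl at -1.91 ± 0.33 (median -0.68, -0.64 at bounds, adjusted p = 0.00929, and adjusted p = 0.0986 with an estimated correlation). Smooth muscle genes had 3 of 8 lower, 4 adjusted over the list alone, with Tagln at -1.34 ± 0.28 (median -1.47, -1.33 at bounds, adjusted p = 0.0109, and adjusted p = 0.114 with an estimated correlation). Heat and oxidative stress genes had 5 of 18 lower, 5 lower and 2 higher adjusted over the list alone, led by Hspb1 (median -1.26, -0.88 at bounds, adjusted p = 0.0489, and adjusted p = 0.388 with an estimated correlation). The unfolded protein response had 4 lower and 2 higher of 24, and 7 and 2 adjusted over the list alone, with Trib3 at -3.56 ± 0.57 (median -0.86, adjusted p = 0.0498, and adjusted p = 0.186 with an estimated correlation). Without the second knockout DMSO array the medians of NF-kB genes, smooth muscle genes, heat and oxidative stress genes and the unfolded protein response were -0.72, -0.85, -0.14 and -0.38, and without the second wild-type DMSO array that of antigen presentation was -1.04.

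Sterol synthesis genes had 3 higher and 1 lower of 25, and 5 and 2 adjusted over the list alone, with Stard4 at 2.90 ± 0.41 and Ch25h at -3.10 ± 0.25. Their median was 0.30 (adjusted p = 0.037, and adjusted p = 0.117 with an estimated correlation), and under median scaling -0.44, which is 0.18 above all genes. It was 0.81 without the second knockout DMSO array. Without the first knockout DMSO array, sterol genes had adjusted p = 0.194, heat and oxidative stress and smooth muscle genes 0.0596, cell death genes 0.127, and matrix, antigen presentation and unfolded protein response genes 0.102. Heat and oxidative stress genes also missed the threshold without the second wild-type DMSO array (0.0633) or the second knockout DMSO array (0.364, median -0.14), and the unfolded protein response without the second wild-type DMSO array (0.0684). Muscle markers, at a median of -1.34 (adjusted p = 0.0602), passed without either wild-type c-di-GMP array (0.0487) or the first wild-type DMSO array (0.0469). Lists that did not pass were immediate early genes (0.128), neural (0.136) and cartilage, fat and bone markers (0.182), the STING and Toll-like receptor list (0.212), p53 targets (0.335), glycolysis and hypoxia (0.853), interferon ligands (0.984) and endothelial markers (0.984). By fry, all 14 lists that passed in camera between genotypes passed, as did muscle (0.0415), neural (0.0102), cartilage, fat and bone (0.00618) and endothelial markers (0.00758), p53 targets (0.013) and positional genes (0.0381).

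**Figure D4:**
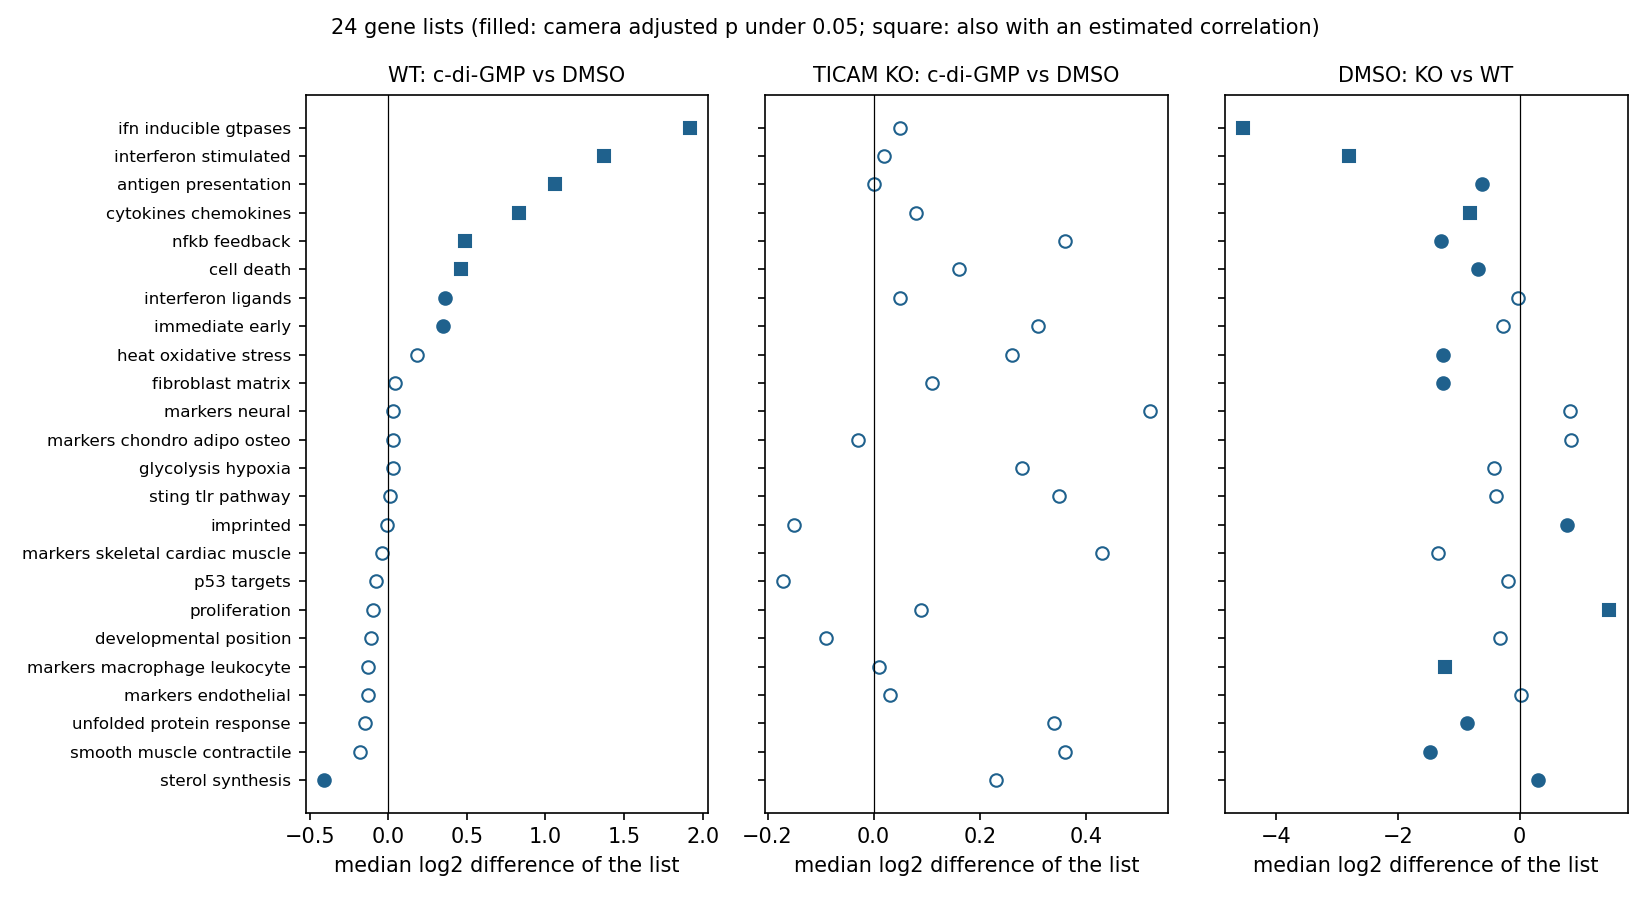
Median log2 difference of each of the 24 tested gene lists in the wild-type response, the TICAM knockout (KO) response and between genotypes under DMSO. Filled symbols have a camera adjusted p under 0.05 and squares keep it with an estimated correlation, on a log2 scale that differs between panels. The interferon-stimulated list lies at 1.37, 0.02 and -2.80.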

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

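Among the results of this part, the tests of the difference of responses were fixed before the data were examined, and every test of an explanation was chosen after the result was seen. The response to c-di-GMP differed between genotypes for 4 genes by limma's test of the difference itself (knockout minus wild type). These were Calhm6 (-5.23, adjusted p = 0.0173), Ifnb1 (-4.70), Oasl1 (-4.12) and Cd274 (-4.47), the last 3 with adjusted p = 0.0419. Calhm6 and Ifnb1 were undetected on both wild-type DMSO arrays, and Calhm6, Ifnb1 and Oasl1 on all 4 knockout arrays, while Cd274 was detected on 1. These are fitted values that rest on readings at background. Calhm6 and Ifnb1 passed the detection filter only through the wild-type c-di-GMP arrays. By camera, the responses of interferon-stimulated genes (median -1.36), interferon-inducible GTPases (-1.75), antigen presentation (-1.05), cytokines and chemokines (-0.80), NF-kB genes (-0.41), interferon ligands (-0.37), cell death genes (-0.11) and the unfolded protein response (0.49) differed too. With all 8 arrays the last 4 lists had adjusted p = 0.207, 0.15, 0.206 and 0.207 with an estimated correlation. Of the 50 interferon-stimulated genes, 29 were undetected in at least 1 of the knockout groups, so their knockout part rests on readings at background.

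The first pattern is that no gene was called in the knockout response. If the weak second knockout DMSO array hid a response, the wild-type risers should respond once it is left out. Their median knockout change was then 0.01, against 2.54 in wild-type cells, but 37 of the 56 were detected on no knockout array. The 14 detected on the other 3 knockout arrays had a median of 0.04, against 2.31 in wild-type cells. For these genes this argues against it. If readings at background hid it, risers detected on the other 3 knockout arrays should respond. Beyond these 14, the set was widened to risers called in wild-type cells without the weak array, 221 of them so detected. Their medians were 0.01 in knockout cells (upper quartile 0.23) and 1.18 in wild-type cells. Wild-type medians of risers are high by selection, so only the knockout medians bear on this question. The test cannot speak for the 37 risers detected on no knockout array. A difference between the cultures, described under the second pattern, was not tested as a cause here and stays open. That c-di-GMP did not enter the knockout cells may be the cause and stays open, as does the genotype itself: limma called 0 genes in knockout cells without that array (221 at an unadjusted p under 0.05), and no measure of uptake was analysed here.

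The second pattern is the low level of interferon-stimulated genes in knockout cells under DMSO. Without the weak array the median of the list was -2.59, so that array is not its source. Leukocytes in the wild-type cultures could add such transcripts: 14 of 20 leukocyte markers on the array were detected on both wild-type DMSO arrays and 1 on the 3 other knockout arrays, with Lyz1 at 12.88, Lyz2 at 11.15 and Adgre1 at 9.61, but Ptprc (4.75), Itgam (4.69) and Tyrobp (5.44), markers named after their values were seen, were not detected on both, and no value here decides. A difference between cultures beyond the targeted gene may be involved and stays open. Without the weak array, 63.3% of 30 positional genes were called between genotypes, against 28.1% of all genes. That fit has 1 knockout DMSO array. These shares count genes and not cultures, so they cannot show how far cultures of the same genotype differ. The genotype stays open as an untested explanation.

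The third pattern is the second knockout DMSO array itself. Its signal at the 99th over the 5th percentile was 7.55, against at least 38.3 on the others, which is consistent with weak hybridisation or poor RNA. A wild-type sample under a knockout label would correlate best with wild-type arrays. Its lowest correlation with a knockout array was 0.0656 above its highest with a wild-type array, which argues against such a label. No biological explanation was tested for this array.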

How the results depend on the processing

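All alternatives were fixed before the data were examined except the authors' values on 7 arrays (without the second knockout DMSO array), chosen after the data were seen. Genes called by limma in wild-type cells (57) numbered 88 without background correction, 0 with median scaling (110 at an unadjusted p under 0.05), 86 with the authors' values, 272 with the wild-type arrays alone, 492 with array weights, 996 with the authors' values on 7 arrays, and 0 to 560 with each array left out. Knockout cells gave 0 under every alternative (7 to 489 at an unadjusted p under 0.05) but those that leave out 1 array, which gave 0 to 5487. The difference of responses (4) was 22 without background correction, 0 with median scaling (72 unadjusted), 15 with the authors' values, 1 with every probe, 0 with trend and robust fitting (519 unadjusted), 1 with array weights, 259 with the authors' values on 7 arrays, and 0 to 4636 with each array left out. Genes between genotypes (1213) numbered 95 with median scaling (3 higher, 92 lower), 104 with the DMSO arrays alone, 274 with array weights, 3283 with the authors' values on 7 arrays, and 270 to 6129 with each array left out. Lists called in the difference (8) numbered 4 with an estimated correlation and 4 to 9 with each array left out, and between genotypes (14) 5 and 4 to 15. The causes of these changes were not tested. Knockout arrays enter the wild-type comparison only through the shared spread, so dropping one left its estimates as they were. The median SE of that comparison was 0.376 with all 8 arrays and 0.198 without the second knockout DMSO array. Counts of lists in the wild-type response (9) stayed between 6 and 10. Of 8209 values of 440 results for named genes under the alternatives, 7231 kept their side of the threshold, 536 lost and 442 gained a call. Among the 7231, 122 changed direction while not called, and 0 called values reversed. For 96 results of lists, 1300 of 1367 values kept their side of the threshold, 48 lost and 19 gained a call. Among the 1300, 74 changed the direction given by the list test while not called, and 0 called values reversed in that direction. A slide block was not run. Low signal over background on the second knockout DMSO array, with a lowest detected log2 of 7.53, limits every comparison that uses it.

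With the replicate number as a block, limma calls numbered 12 in wild-type cells, 0 in knockout cells (283 at an unadjusted p under 0.05), 0 for the difference of responses (419) and 940 between genotypes. Called lists numbered 9, 0, 7 and 14. Arrays of the same number showed no large joint deviation over all genes (correlations of -0.03 to 0.06 over the 6 pairs of groups). The labels do not say whether they shared a day or batch, and this check cannot exclude it.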

Other observations

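The genes, neighbours and comparisons of this paragraph were chosen after their values were seen, apart from Cdkn2b, which was named by rule. Knockout cells lacked signal from both cell cycle inhibitor genes of the locus that limits the growth of cultured fibroblasts. Cdkn2b read 11.67 ± 0.09 (log2, SD, n = 2) and Cdkn2a 10.90 ± 0.31 in wild-type cells under DMSO. Both were detected on all 4 wild-type arrays and on 0 of the 4 knockout arrays, at least 37.4-fold and at least 21.9-fold lower (limma adjusted p = 4.53e-05 and 0.000369). Cdkn2a has 2 probes, neither of which was detected on a knockout array. In the order of the reference gene table these are adjacent protein-coding genes. Mtap, the protein-coding neighbour on the side of Cdkn2a, was detected on all 4 knockout arrays, with a difference of 0.26 ± 0.57 (adjusted p = 0.778, and 0.00561 without the second knockout DMSO array, at 1.21). Dmrta1, the neighbour on the other side, was detected on 0 of the 8 arrays.

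Imprinted genes were higher as a list in knockout cells under DMSO in camera with the preset correlation, and single positional genes differed while their list did not pass. Both lists were fixed before the data were examined. Of 8 imprinted genes 3 were higher in knockout cells, also 3 adjusted over the list alone: Igf2 (4.74 ± 0.32), Dlk1 (4.92 ± 0.38) and Slc38a4 (at least 15.9-fold). Their median was 0.77, or 0.49 at bounds (camera adjusted p = 0.0229, and adjusted p = 0.117 with an estimated correlation). Without the first knockout DMSO array the median was 0.21 (adjusted p = 0.102). Without the second it was 1.35, with 4 of the 8 genes higher (adjusted p = 0.084). Of 30 positional genes 5 were higher and 6 lower, and 8 and 10 adjusted over the list alone (camera adjusted p = 0.984), with a median of -0.33 and a mean of 0.09. Hoxd8 was at least 32.9-fold higher and Meox1 at least 7.48-fold higher, and Hoxb7 stood at -2.65 ± 0.24. Of these, Hoxd8 and Meox1 were not detected on either wild-type DMSO array.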
